A study of Mus musculus with 36 samples.

How the data were processed

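Contacts of 4 gene loci were measured by UMI-4C in mouse cells. UMI-4C ligates DNA ends that lie close together in the nucleus, reads out what is joined to a chosen fragment (the viewpoint) and counts ligation events with molecular identifiers. The viewpoints lie at Foxa2, Gata4, Gata6 and T, and each was read in Whsc1+/+ (WT) and Whsc1-/- (KO) embryonic stem cells (ES) at day 0 and in embryoid bodies (EB) at day 6. The labels list 32 contact libraries, 2 for each of 16 combinations of viewpoint, genotype and stage. They also list 4 RNA-seq libraries of ES, 2 per genotype, which were not analysed here, so expression of Whsc1 itself could not be used to check the genotype labels.

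The values are contact scores made by the authors, 1 column for each stage and genotype at positions around 1 viewpoint, per the file headers. The labels' 2 libraries of a group therefore share 1 column, and 16 columns were used in all. The scores take both signs, fall with distance and change smoothly from position to position, as smoothed values on a log scale would, but the unit, the log base, the smoothing and the scaling are not given in the sources used here. No counts could be recovered from the values, so the depth is unknown, and no interval or detection floor was computed. Per the submitters' processing notes, the genome build was mm10, and BWA, STAR and deepTools were among the tools, with no role or version stated. Infinite scores, all within 3 kb of a viewpoint, were treated as missing.

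Within each genotype the mean difference between EB and ES over the windows of a viewpoint lay between -0.035 and 0.026. The WT pair of columns shares its missing positions at each viewpoint, and so does the KO pair. The pairs thus look scaled to each other within a genotype, while the WT and KO columns look scaled separately. Differences between stages within a genotype were therefore taken as they are, and differences between genotypes are also given after removing the median difference over the windows of that viewpoint (centring).

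Positions with a score in all 4 columns were averaged in 10 kb windows counted outward from the viewpoint. Positions under 10 kb from the viewpoint were left out of the windows, and a window needed at least 10 positions. The limit of 500 kb was never reached, since the tables end between 199 and 242 kb from the viewpoint. This left 161 windows, 38 at Foxa2, 41 at Gata4, 40 at Gata6 and 42 at T. At Foxa2, where 94 positions lack a KO score, the windows on the higher side end at 160 kb. Comparisons of the 2 sides of Foxa2 therefore leave out lower-side windows further away, such as those at 190 to 210 kb. Sides are named by coordinate, because the gene table used here gives no strand: the lower side has coordinates below the viewpoint and the higher side above it. Gene spans came from the RefSeq table of GRCm38.p6, a patch release of the assembly that mm10 represents, and a span's value is the mean over its positions, with at least 10 required. Unlike the windows, the spans keep positions under 10 kb from the viewpoint. Values were found for 29 genes. Foxa2 itself had 1 usable position and Prr18 had 8, so neither has a span value.

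The design fixed before the data were examined called for a count model with 2 libraries per group and for permutation tests of the distal and lower-side shares of contacts, and for values side by side with a rule of size if the libraries turned out pooled. The columns are pooled and hold no counts, so no test between conditions was made and no p-value is given. A difference was counted where it reached 0.5 score units, a size chosen after the values were seen. The 2 shares were replaced by differences of mean scores, namely windows from 50 kb outward minus nearer windows, and lower minus higher side over windows present at the same distance on both sides. The 5 comparisons were EB against ES in WT, EB against ES in KO, KO against WT in ES, KO against WT in EB, and the difference between the stage differences of the genotypes. Windows were named by a rule fixed in advance and adapted to scores: the 5 with the highest mean over the 4 columns from 50 kb outward at each viewpoint, and in each comparison and viewpoint the 5 with the greatest difference of at least 0.5, or, where none reached it, the 2 greatest, given as values. The spans of protein-coding genes replaced the windows of their start sites. Neighbouring windows that passed the size were joined into blocks.

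The alternatives were windows of 5 and 20 kb, 2 or 20 kb left out at the viewpoint, a span of 200 kb, distal windows from 100 kb, and leaving out the windows with a mean score below the median, all fixed in advance. Centring, window medians, no minimum of positions, sizes of 0.3 and 0.75 and leaving out each viewpoint were added after the values were seen. The counting of windows was tested on simulated profiles of EB against ES in WT. There 48 of 168 windows were changed, 48 were recovered and 0 were wrongly counted. The simulated changes were all larger than the size required and the simulated noise was small, so full recovery was close to certain. That test checked the counting step only. It cannot show how reliable the windows counted in the real columns are, because the noise and depth of those columns are not known. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.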

Results

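The series addresses how Whsc1, also known as Nsd2, a methyltransferase that acts on lysine 36 of histone H3, relates to transcription factors of mesoderm and endoderm. Foxa2 is a forkhead factor of endoderm, Gata4 and Gata6 are zinc-finger factors of endoderm and heart, and T (Brachyury) is a T-box factor of mesoderm. Contacts of these 4 loci were compared between ES at day 0 and EB at day 6, in cells with and without Whsc1. Embryoid bodies are aggregates in which embryonic stem cells differentiate once removed from conditions that keep them pluripotent. In mm10 the viewpoints lie at position 148046914 of chromosome 2 (Foxa2), 63245606 of chromosome 14 (Gata4), 11053621 of chromosome 18 (Gata6) and 8433756 of chromosome 17 (T). Each stage and genotype has 1 pooled column of scores per viewpoint, with between 983 and 1085 usable positions. No replicate values, errors or depths can therefore be given, and every difference below is a difference between single profiles in score units.

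Contact scores fell steeply with distance at all 4 loci, and each locus had its own shape. Over the Gata4 gene (chromosome 14, 63198914 to 63271712), a span that holds the viewpoint, the mean score was 2.47 in ES WT. It was -0.12 over Ctsb, a lysosomal protease gene whose span begins 99.7 kb away on the lower side. Among distal windows, the ones with the highest mean over the 4 columns at Gata4 lay in Neil2, a DNA glycosylase gene, and on the higher side mostly in the transcript Gm4151, at mean scores from 0.92 to 0.99. At Foxa2 they lay mainly in the long non-coding RNA 9030622O22Rik on the lower side, with the highest at 0.74. At Gata6 all 5 were on the lower side in or overlapping the long non-coding RNA Gm35814 (chromosome 18, 10888414 to 10997808), from 0.14 to 0.55. At T all 5 were on the lower side, with the highest at 0.22 in T2, a gene next to T. The profiles were asymmetric: in ES WT the lower side exceeded the higher side by 0.73 at Foxa2, 0.42 at Gata6 and 0.62 at T, while Gata4 had -0.34.

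**Figure D1:**
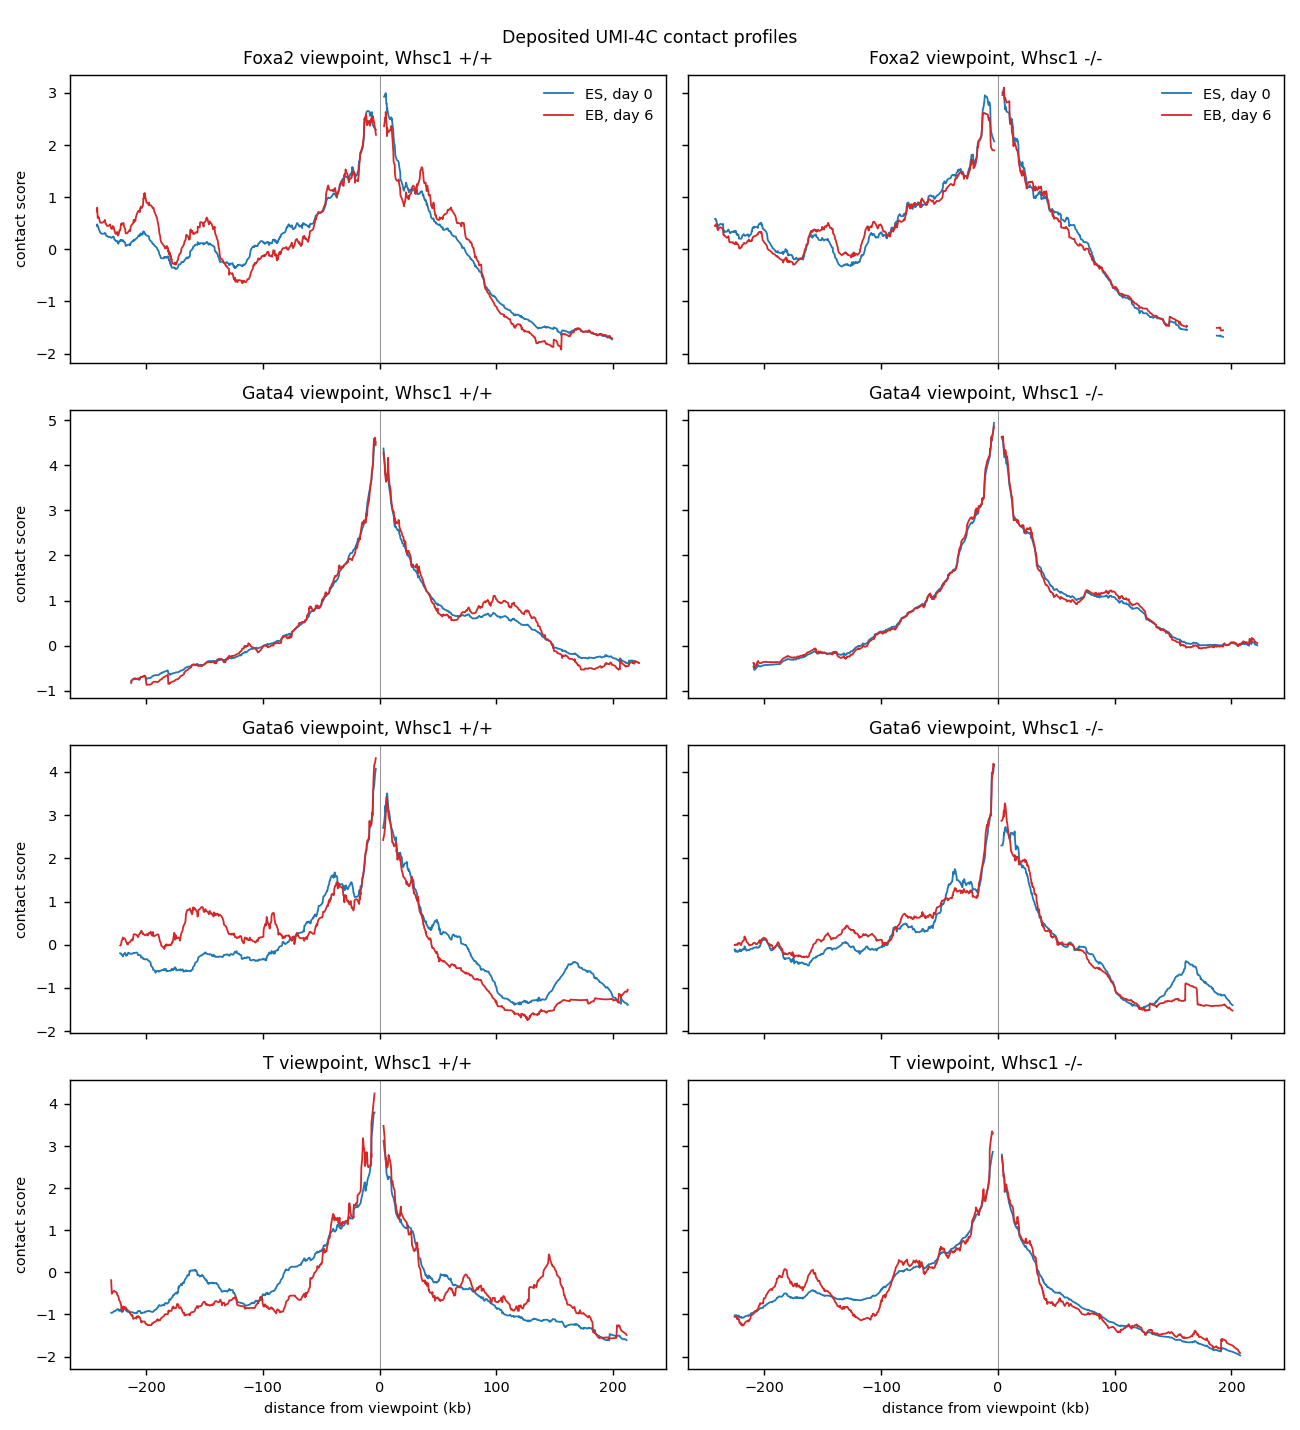
Deposited contact scores (vertical axis, score units) against distance from the viewpoint in kb (horizontal axis) for the 4 viewpoints, WT on the left and KO on the right, with ES at day 0 in blue and EB at day 6 in red. In WT the Gata6 profile of EB lies above that of ES from 130 to 210 kb on the lower side, by a mean of 0.84, and the T profile of EB has a peak from 130 to 160 kb on the higher side that ES lacks.

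In WT cells, contact profiles of Gata6 and T differed most between ES and EB. At Gata6, scores were higher in EB along 80 kb on the lower side, from 130 to 210 kb away (chromosome 18, 10843621 to 10923620), by a mean of 0.84 and by 1.22 in the window at 160 to 170 kb, in a region that holds part of Gm35814 and Gm18764. On the higher side of Gata6, where no annotated gene lies in these blocks, EB minus ES was -0.60 on average from 40 to 80 kb and -0.67 from 150 to 190 kb, or -0.37 and -0.43 after centring, which put all but 1 of the lower windows at Gata6 under 0.5. At T, scores were higher in EB from 130 to 160 kb on the higher side (chromosome 17, 8563756 to 8593755), by a mean of 1.03 and by 1.34 at 140 to 150 kb. This block lies within the span of Pde10a, a cyclic nucleotide phosphodiesterase gene. On the lower side of T, EB minus ES was -0.75 from 60 to 90 kb, over part of T2 and the edge of Prr18, and -0.72 from 140 to 170 kb, over parts of Gm33799 and of Mpc1, which encodes a subunit of the mitochondrial pyruvate carrier.

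Foxa2 and Gata4 differed less between the stages in WT. At Foxa2, 2 windows from 190 to 210 kb on the lower side (chromosome 2, 147836914 to 147856913), with no annotated gene, were higher in EB by a mean of 0.60. No window of Gata4 reached 0.5, and the greatest differences were 0.33 and 0.32 at 100 to 120 kb on the higher side, around the end of Gm4151. Near the T viewpoint, the window at 10 to 20 kb on the lower side was higher in EB by 0.58, and the T gene itself (chromosome 17, 8434423 to 8442496) by 0.21. The window at 10 to 20 kb also overlaps T2, so parts of T2 differed in opposite directions, and its whole span had -0.15. The span of T lies wholly within 10 kb of the viewpoint, among positions that the windows leave out. The spans of Gata4 and Gata6 differed by 0.038 and -0.19. Of the protein-coding spans further out, the greatest differences were -0.48 at Mpc1, 0.42 over the part of Pde10a that was covered, and -0.28 at Ccr6, a chemokine receptor gene. Ctsb, Fdft1, Neil2, Blk and Fam167a, all near Gata4, lay between -0.12 and 0.057.

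In all, 29 of 161 windows (18.0%) differed by at least 0.5 between EB and ES in WT, 15 higher and 14 lower in EB. They were 17 at Gata6, 10 at T and 2 at Foxa2. The mean difference at each viewpoint was near 0, so higher and lower windows balance in part by arithmetic. Centring, added after the values were seen, gave 21 higher and 6 lower, mainly through Gata6, where the median difference was -0.23, and leaving out Gata6 gave 9.92% of the remaining windows.

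**Figure D2:**
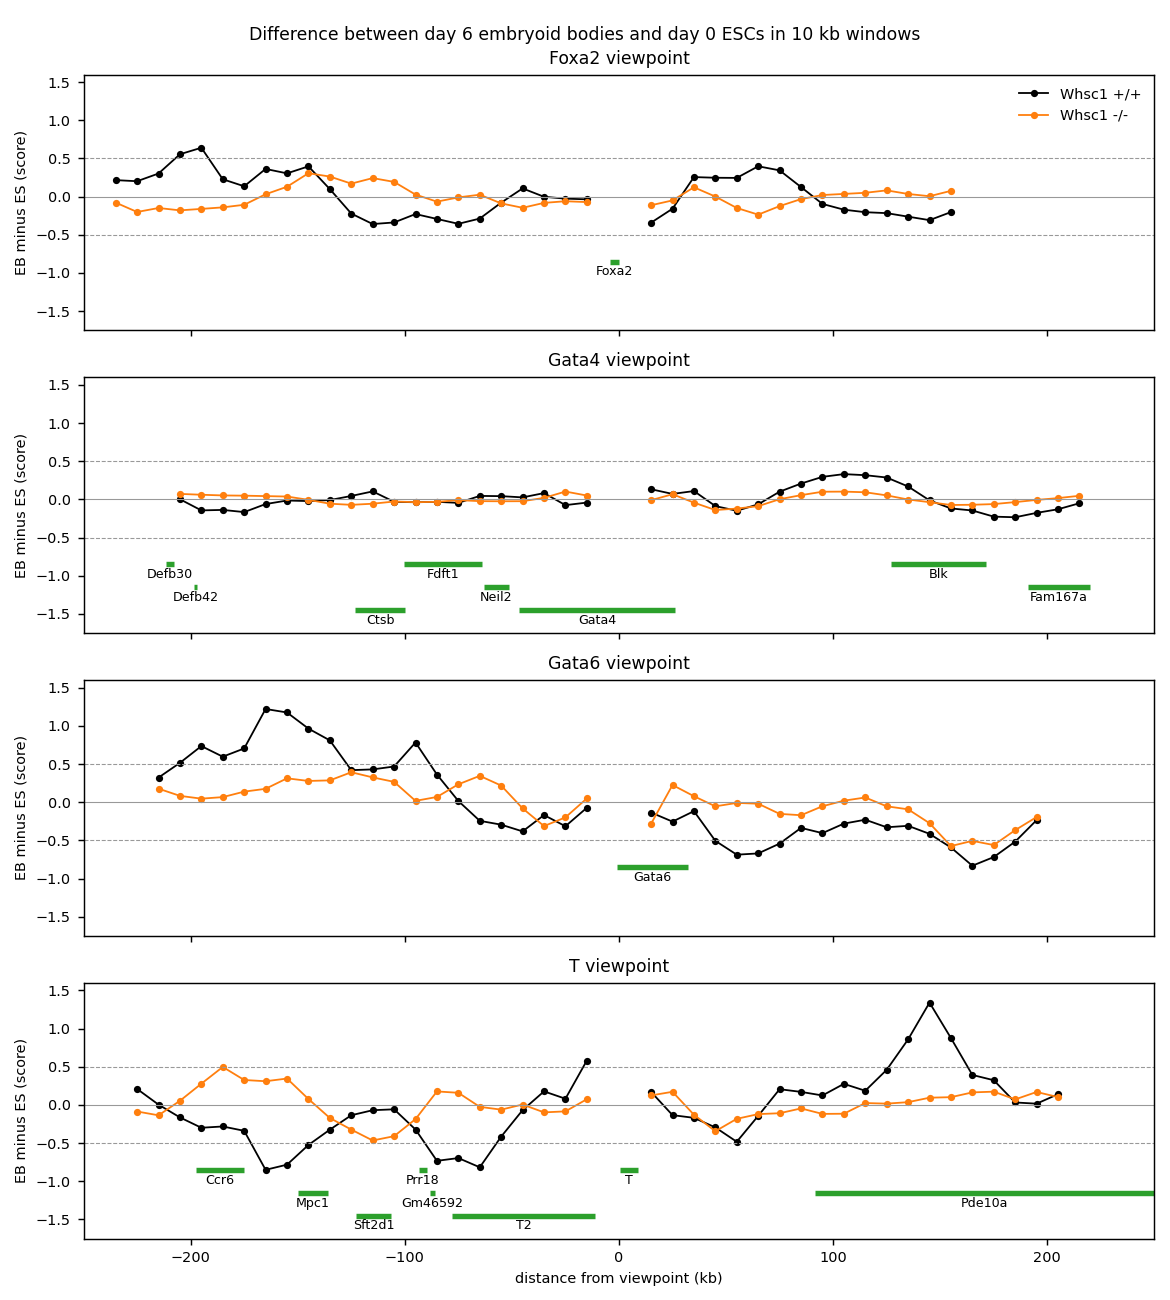
Difference in mean contact score between EB at day 6 and ES at day 0 (vertical axis, score units) in 10 kb windows against distance from the viewpoint in kb (horizontal axis), WT in black and KO in orange. Dashed lines mark 0.5 and -0.5, and green bars are protein-coding genes of RefSeq that overlap the covered positions. The WT difference reaches 1.22 at Gata6 and 1.34 at T, where the KO differences in the same windows are 0.18 and 0.095.

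In KO cells the same loci differed less between stages. Only 3 windows (1.86%) reached 0.5, all lower in EB and all at 150 to 180 kb on the higher side of Gata6 (chromosome 18, 11203621 to 11233620), where the mean was -0.55 in KO and -0.71 in WT. Along the lower-side block of Gata6 that was higher in WT EB, the KO difference was 0.17. Over the Pde10a block at T it was 0.078, and over the Foxa2 block at 190 to 210 kb it was -0.17. At the other 3 viewpoints no window reached 0.5 in KO. The 2 greatest differences of each were 0.498 in Ccr6 and -0.47 in Sft2d1 at T, 0.31 and 0.26 at 130 to 150 kb on the lower side of Foxa2, and -0.14 and -0.12 at 40 to 60 kb on the higher side of Gata4. Over whole spans, Ccr6 had 0.41 and Sft2d1 -0.45 in KO, against -0.28 and -0.082 in WT.

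Setting the stage differences of the genotypes side by side, 26 windows reached 0.5 in WT alone, 0 in KO alone and 3 in both, with the same sign. The WT difference was the greater in absolute size in 131 of 161 windows, 32 at Foxa2, 31 at Gata4, 36 at Gata6 and 32 at T. Its SD across windows was 0.28 in WT and 0.13 in KO at Foxa2, 0.14 and 0.061 at Gata4, 0.56 and 0.25 at Gata6, and 0.46 and 0.20 at T. These SDs describe the unevenness of a profile along the chromosome and are not replicate errors. The stage difference of KO minus that of WT reached 0.5 in 30 windows (18.6%), 15 in each direction, and in 28 after centring. The greatest of these were -1.25 in Pde10a at 140 to 150 kb and 1.16 in Gm33799 at 160 to 170 kb, on opposite sides of T. At Gata6 the greatest was -1.05 at 160 to 170 kb on the lower side, and at Foxa2 it was -0.80 at 190 to 200 kb on the lower side. At Gata4 none reached 0.5, and the greatest values were -0.23 in 2 windows at 100 to 110 and 120 to 130 kb on the higher side. These differences between genotypes could not be tested.

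The balance between the sides of a viewpoint differed with stage at Gata6 and T. At Gata6 the excess of the lower over the higher side was greater in EB than in ES by 0.81 in WT and by 0.30 in KO. At T this contrast was -0.52 in WT and 0.020 in KO. At Foxa2 it was -0.065 and 0.074, and at Gata4 -0.057 and 0.016. Averaged over the genotypes, the difference with stage was 0.55 at Gata6, -0.25 at T, 0.0044 at Foxa2 and -0.021 at Gata4. Relative to nearer windows, distal windows were higher in EB than in ES by 0.30 at Gata6 in WT and by 0.087 in KO, and at the other 3 viewpoints this contrast lay between -0.097 and 0.053. At T its average over the genotypes, -0.022, became 0.15 with distal windows taken from 100 kb. With genotype, KO minus WT of the lower-minus-higher contrast was 0.25 in ES and 0.79 in EB at T, 0.24 and -0.27 at Gata6, 0.051 and 0.19 at Foxa2, and -0.015 and 0.058 at Gata4. The opposite signs at Gata6 average to -0.018, against 0.52 at T. KO minus WT of the distal contrast was 0.11 in ES and 0.26 in EB at T, 0.12 and -0.099 at Gata6, -0.12 and -0.094 at Gata4, and -0.046 and -0.022 at Foxa2. The average of 0.18 at T became -0.0068 with distal windows taken from 100 kb, and that of 0.0086 at Gata6 became -0.12.

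In ES, scores were higher in KO in 41 of 41 windows at Gata4, with a median of 0.30, and the 3 windows that reached 0.5 lay near the viewpoint and overlap Gata4 itself, at 0.57, 0.56 and 0.55. At Foxa2 the median was 0.17, with the greatest values 0.44 and 0.41 in 9030622O22Rik. At T the median was -0.28, and the greatest values were -0.48 in 2 windows at 20 to 30 and 70 to 80 kb on the higher side. At Gata6 the median was 0.047, and the differences ran from -0.29 to 0.46, with the greatest values 0.46 in Gm18764 and 0.45 in Gm35814, both on the lower side. Because the WT and KO columns look scaled separately, these levels cannot be read as gains or losses of contact, and after centring the named windows had 0.26, 0.25 and 0.25 at Gata4, 0.27 and 0.23 at Foxa2, -0.20 and -0.20 at T, and 0.41 and 0.40 at Gata6. The greatest centred difference at T was then 0.48, at 180 to 190 kb on the lower side in Ccr6.

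In EB, the difference between KO and WT reached 0.5 in 37 windows (23.0%), 19 higher and 18 lower in KO. This comparison, EB against ES in WT and the difference between the stage differences all use the same EB WT columns. Their counts and shared blocks are therefore not independent of each other. EB against ES in KO and KO against WT in ES, which do not use those columns, had 3 windows each. At T, KO minus WT was -1.64 at 140 to 150 kb on the higher side within Pde10a, in a block from 120 to 180 kb with a mean of -0.98, or -1.37 and -0.71 after centring. On the lower side of T, scores were higher in KO by 1.05 at 80 to 90 kb, beside Prr18, and by 0.98 at 180 to 190 kb, in Ccr6, or by 1.32 and 1.25 after centring. At Gata6, KO minus WT was -0.74 from 140 to 170 kb on the lower side, in Gm35814, and 0.51 at 60 to 70 kb, or -0.86 and 0.39 after centring. At Foxa2 it was -0.81 at 190 to 200 kb on the lower side and 0.79 at 110 to 120 kb, both without an annotated gene, or -0.97 and 0.63 after centring. At Gata4 the greatest value was 0.73, at 20 to 30 kb on the lower side within Gata4, or 0.42 after centring. After centring, 27 windows reached 0.5, 15 higher and 12 lower, and 0 of these were at Gata4. Without T, 13.4% of the remaining windows reached 0.5 before centring.

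**Figure D3:**
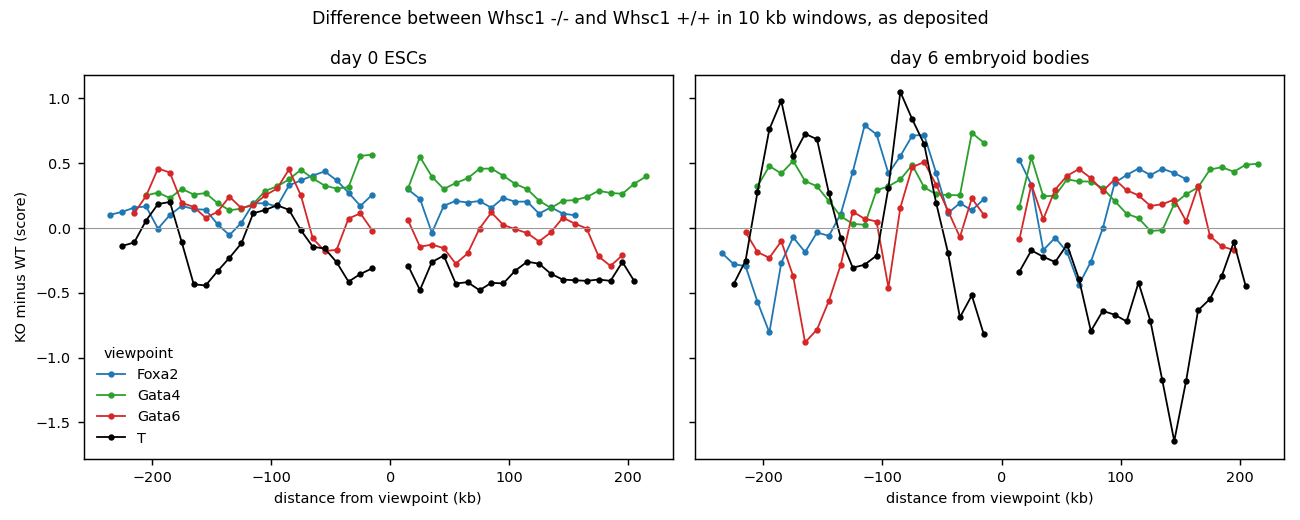
Difference in mean contact score between KO and WT (vertical axis, score units, as deposited) in 10 kb windows against distance from the viewpoint in kb (horizontal axis), for ES at day 0 on the left and EB at day 6 on the right, with 1 colour per viewpoint. In ES the Gata4 line lies above 0 in 41 of 41 windows and the Gata6 line runs from -0.29 to 0.46, and in EB the T line reaches -1.64.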

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

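All the tests in this part were chosen after the values were seen. At T, 3 neighbouring windows on the lower side differed in opposite directions with stage in the 2 genotypes, by at least 0.3 each way as deposited. After centring this held only at 150 to 160 kb, since the WT difference at 170 to 180 kb became -0.28 and the KO difference at 160 to 170 kb became 0.29. The stage difference of KO exceeded that of WT by 1.13 at 150 to 160 kb, by 1.16 at 160 to 170 kb and by 0.67 at 170 to 180 kb. The scores change smoothly along the chromosome, so neighbouring windows cannot be taken as 3 independent observations, and with 1 pooled column per group the difference was not tested.

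The stage difference was more uneven along the chromosome in WT than in KO at all 4 viewpoints, with SD ratios of 2.13 at Foxa2, 2.36 at Gata4, 2.25 at Gata6 and 2.27 at T. Broader smoothing of the KO columns could flatten the 10 kb windows of ES KO. The slope of KO on WT about the distance decay was at least 0.998 at every viewpoint, so no such flattening was seen in ES. That slope also carries broad features, such as the excess of one side over the other, which smoothing over short spans would leave in place. It therefore cannot exclude smoothing over short spans. From position to position, the roughness of ES KO relative to ES WT was only 0.40 at T, against 1.19 at Foxa2, 1.16 at Gata4 and 0.95 at Gata6. In EB the order differed. There the roughness of KO and WT was 0.0096 and 0.016 at Gata6 and 0.013 and 0.016 at Foxa2. It was 0.0089 and 0.0070 at Gata4, and 0.011 and 0.0091 at T. Uneven EB WT libraries stay open, since depth and replicates are not known. The WT and KO stage differences correlated above every shift of one along the other at 0 viewpoints. Because the scores change smoothly, shifts by a few windows can keep much of a correlation, so this count does not decide the question. The 2 differences had the same sign in 33 of 40 windows at Gata6 and 24 of 41 at Gata4. At T it was 23 of 42 and at Foxa2 14 of 38. The roughness of EB relative to ES in WT was 1.40 at Foxa2, 1.30 at Gata4, 1.20 at Gata6 and 0.87 at T. These lie under the 1.5 set as a sign of noise from uneven libraries, and in KO the values were 0.97, 1.43, 0.76 and 2.62. Roughness compares neighbouring positions of scores that already change smoothly. It cannot show unevenness spread over wider spans, so staying under 1.5 decides nothing here. A dependence of contact rearrangement on Whsc1 is one biological candidate explanation, and it cannot be told apart from such noise here. The sample titles give stage, genotype and day but not the cell types within the EB. A difference between the genotypes in the make-up or differentiation of the EB therefore cannot be told apart from it either.

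Between separately scaled pairs of columns, a shift of scale would set KO apart from WT by 1 constant along each viewpoint. In ES the mean made up 0.90 of the mean squared difference at Gata4, 0.73 at Foxa2 and 0.57 at T, values that leave such a shift open, and a real and uniform difference would look the same. At T a shift could be only part of the difference between these columns, whose windows ran from -0.48 to 0.20. The lower-minus-higher contrast, which no constant changes, differed there by 0.25. At Gata6 the share was 0.057, so the difference there was mostly not one of level. A small mean also lowers this share. The SD across windows was 0.19 at Gata6 and 0.21 at T, against 0.11 at Foxa2 and 0.11 at Gata4. The mean of KO minus WT was similar in EB and ES, at 0.14 and 0.18 for Foxa2, 0.31 and 0.32 for Gata4, and -0.19 and -0.24 for T, but this follows from stage differences that average near 0 within each genotype and decides nothing. In EB, 27 windows still reached 0.5 after centring, which no constant accounts for.

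In WT, gains on one side of Gata6 and T stood beside losses on the other, with opposite signs in 13 of 19 mirrored pairs of windows at Gata6 and 16 of 20 at T, against 16 of 19 and 7 of 20 in KO, and 8 of 15 at Foxa2 and 11 of 20 at Gata4 in WT. Scaling each distance band to a common total over both sides could make such mirror images. If the bands matched the 10 kb windows, 1 shift common to all bands, or none, would have to lie between the lower- and higher-side difference of every pair. At Gata6 the pair at 10 to 20 kb needs a shift of at least -0.14 and that at 40 to 50 kb one of at most -0.38, a gap of 0.25, and at T the gap was 0.59, between pairs at 10 to 20 and 50 to 60 kb. This argues against scaling in bands of 10 kb as the whole cause, alone or with an overall shift. The width of any such bands is not known. With bands of another width a pair can move the same way on both sides, so such scaling stays open. The gap in WT was also 0.32 at Foxa2 and 0.27 at Gata4. The mean of EB minus ES in WT was -0.0018 at Gata6 and -0.035 at T, so gains in some windows came with losses in others by arithmetic. The losses are therefore not findings independent of the gains, although a mean near 0 does not set the side on which they fall. Scaling of whole profiles to 1 total was not tested, unequal libraries remain open as above, and a rearrangement of contacts on differentiation remains a hypothesis.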

How the results depend on the processing

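No paired analysis was possible because each column pools the libraries of its group and carries no replicate number; leaving out libraries, library-size scalings, other count tests, count filters, pseudocounts, fits on single contrasts, p-value adjustments and scaling to all contacts were not run for the same reason. With no replicates or depth, a percentage of windows was called moved beyond 1.5 times and a score contrast beyond 0.1 score units. Of 75 alternative percentages, 55 stayed within that factor and 20 did not. For EB against ES in WT, KO against WT in EB and the difference between the stage differences, all alternatives fixed in advance stayed within it. The percentages followed the size required: at 0.3 they were 38.5% and 11.2% for EB against ES in WT and KO, 32.3% and 53.4% for KO against WT in ES and EB, and 34.8% for the difference between stage differences, and at 0.75 they were 7.45%, 0%, 0%, 8.07% and 8.07%. Leaving out Gata6 gave 9.92% in WT and 0% in KO for the stages, leaving out Gata4 gave 0% for KO against WT in ES, and leaving out T gave 13.4% in EB. The 2 results that rest on 3 windows moved most: EB against ES in KO was 1.18% with 20 kb windows and 0% without the windows of lower mean score, and KO against WT in ES was 1.18%, 3.70% in the same settings, 2.96% with 2 kb left out and 0% after centring. Of 88 alternative contrasts, all averaged over the genotypes or over the stages, 85 stayed within 0.1. The contrasts within 1 genotype or 1 stage were not varied. With distal windows taken from 100 kb, the genotype contrast became -0.12 at Gata6 and changed sign at T from 0.18 to -0.0068, and the stage contrast at T became 0.15; the cause was not tested. Of 134 alternative values of named windows, 98 stayed within 0.1, 36 moved further and 0 changed sign.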

Other observations

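All the values in this part were chosen after the data were seen. Averaged over the viewpoints, the SD across windows of the difference between EB WT and another column was 0.36 for ES WT, 0.38 for ES KO and 0.38 for EB KO. The other pairs had 0.15 for ES WT and ES KO, 0.16 for ES KO and EB KO, and 0.23 for ES WT and EB KO. Gata6 departed from this order: there EB KO was nearer to EB WT, at 0.33, than to ES WT, at 0.36.

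The spans of long non-coding RNA genes with enough positions are all given here as EB minus ES, and those that overlap a block described above share its positions. At Gata6, Gm35814 had 0.51 in WT and 0.23 in KO, 9130001E16Rik had -0.34 and 0.092, and Gata6os had 0.062 and 0.084. At T, Gm33799 had -0.59 in WT and 0.30 in KO, 4930506C21Rik had -0.24 in both, and Gm16702 had -0.24 and 0.026. At Gata4, Gm36165 and Gm46458 on the higher side had 0.31 and 0.30 in WT and 0.077 and 0.087 in KO, while on the lower side Gm35908 had -0.13 and 0.041 and Gm36025 had -0.014 and 0.0075. At Foxa2, Gm35528 and Gm35579 had 0.38 and 0.34 in WT and 0.042 and 0.14 in KO, 9030622O22Rik had -0.15 and -0.051, and Gm36597 had -0.24 and 0.068.

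The WT and KO stage differences correlated across windows with Pearson's r of 0.65 at Gata6, 0.42 at Gata4, -0.086 at T and -0.35 at Foxa2. Sliding one profile along the other gave as high an r in 3 of 39 shifts at Gata6, 3 of 40 at Gata4, 24 of 41 at T and 31 of 37 at Foxa2. Windows are not independent replicates, and no p-value is attached.

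Within 10 kb of the viewpoint, on the higher side of Gata6, KO was -0.56 against WT in ES and 0.0085 in EB. On its lower side the values were 0.044 and 0.0067. At T they were -0.60 and -0.53 on the lower side and -0.37 and -0.62 on the higher. Gata4 had 0.46 and 0.48, then 0.43 and 0.46, and Foxa2 had 0.079 and -0.17, then 0.039 and 0.53. These values are not centred, and because the WT and KO columns look scaled separately they cannot be read as gains or losses of contact.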
